A study of Mus musculus with 2 samples.

How the data were processed

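Single cells from E12.5 mouse placenta were profiled by droplet sequencing with molecular identifiers (UMIs) in 2 libraries, 1 from wild-type placenta (control) and 1 from placenta of the genotype Elf5-Cre; Slc25a1f/f (Slc25a1 conditional knockout). Each file holds raw UMI counts per matrix row and cell barcode, as deposited. The matrices were written by Cell Ranger 7.1.0, per the file headers. Reads were mapped to mm10, per the submitters' processing notes, and the labels' protocols describe default parameters, a first selection of barcodes by Cell Ranger and a later filter in Seurat that kept cells with at least 200 detected genes. Neither selection had been applied to the deposited counts, because 76.0% of the control barcodes and 74.1% of the knockout barcodes held at most 2 UMIs.

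A matrix row stands for 1 gene. The names of the rows were not used here, because the matrices give row numbers only, and a name was never read from a row's place in a reference annotation. The level of Slc25a1, the gene lists and the cell type markers that had been fixed before the data were examined were therefore not analysed here. Clusters were called by number, and at most 2 rows in each direction were named, by row number. The rule for named rows, also fixed beforehand, took the 2 rows with the largest ratio in each direction among those past the rule of size over all cells. One further row, the most abundant of each library, was described without its number and was chosen after its values were seen.

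The filter fixed beforehand, 200 detected rows per barcode, left 78306 barcodes of the control and 75749 of the knockout, with medians of 527 and 519 UMIs. Most of these lay in a narrow peak between 300 and 600 UMIs and were taken as empty droplets that hold free RNA. A cell was instead defined as a barcode of at least 2000 UMIs, a minimum chosen after seeing the distribution of UMIs per barcode. The filter as first written was kept as an alternative. Scrublet, run per library in scanpy 1.11.5 with an expected doublet rate of 6%, marked 3 barcodes in each library, which is 0.0331% of the control and 0.0322% of the knockout. A caller that marks so few has not worked, so doublets have to be taken to remain among the cells. An alternative removed the 6% of barcodes with the highest doublet scores in each library.

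Counts of each cell were scaled to 10000, log(1 + x) transformed and reduced to 30 principal components of the 2000 most variable rows. Rows detected in fewer than 4 cells were left out of that choice. Each cell was linked to its 15 nearest neighbours, neighbours were weighted by their shared neighbours, and clusters were drawn with Leiden at resolution 1 (leidenalg 0.10.2, igraph 0.11.9) over both libraries together, without batch correction. Clusters were numbered by size. They were grouped into families by average linkage of the correlations between their mean log profiles, each row centred over clusters, over 8737 rows, and the tree was divided where the average correlation fell below 0, a choice made after seeing the data. NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Python 3.11.15 were used throughout, and matplotlib 3.10.9 for the plots.

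With 1 library per genotype there was no replicate and no test between genotypes, and no p-value was computed. Both values of each comparison are given, a share of cells with its exact (Clopper-Pearson) 95% binomial interval and a sum of UMIs with its exact 95% Poisson interval. These intervals cover counting error only. They leave out the variation between animals, dissociations and captures, and those of UMI sums also leave out the variation between cells. A share was called larger or smaller where the ratio between libraries was at least 1.5 and the intervals did not overlap. Levels are in CPM, the UMIs of a row summed over cells per 1000000 summed UMIs. A row was past the rule of size where its CPM differed at least 2-fold, it reached at least 50 CPM in 1 of the libraries, and the exact 95% interval of the ratio, from the binomial interval of the split of its UMIs, excluded 1. A side with 0 UMIs was set to 3 UMIs. Inside clusters the same rule was applied where each library had at least 50 cells. The number of rows that counting error alone puts past the rule was found by drawing both libraries from their pooled profile at their own totals, 50 times. These draws treat UMIs as independent, although the UMIs of a row can lie in few cells.

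The control library held 149392415 UMIs and the knockout library 141906904, over 32285 rows, of which 7305 and 6936 had no UMI. After the minimum of 2000 UMIs, 105344182 and 96222805 UMIs remained in cells. Summed over all cells, a row at 50 CPM therefore had a counting error small against a 2-fold ratio, whereas the smallest cluster sums compared held 305017 and 226155 UMIs. The rule was tested on simulated counts with 200 rows changed 3-fold among 3691 rows over all cells. It recovered 100% of them and no unchanged row passed. In cluster 22, the shallowest, it recovered 85% of 200 rows changed 3-fold among 3779, and 114 unchanged rows passed. The clustering was tested on 2000 simulated cells of 5 profiles at resolution 0.3 and returned 5 clusters with an adjusted Rand index of 1. The profiles were those of 5 picked clusters, at a single depth each and without variation between cells of a profile. The test therefore says nothing about closely related clusters or about the resolution of 1 used for the data.

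Alternatives changed the minimum for a cell, the treatment of doublets, the number of variable rows and of principal components, the Leiden resolution, the depth of each cell, the library from which clusters were drawn, the scaling (edgeR 4.0.16 for trimmed mean of M values, TMM, and DESeq2 1.42.0 for the median of ratios, both only for scaling factors, in R 4.3.3), the level and ratio in the rule, the weight of each cell, the mix of clusters and the subtraction of free RNA. Free RNA was taken as the profile of the empty droplets, at their median of 494 UMIs in the control and 483 in the knockout, times the number of cells. Alternatives for the minimum of UMIs, the doublet scores, free RNA, the equal thinning of clusters, the minimum of 100 cells, the clustering without rows past the rule and the giving of every cluster to a family were added after seeing the data. Other scalings that had been foreseen for Slc25a1 and for the gene lists were not run, because rows were not named.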

Results

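Placentas of wild-type mice and of mice in which Slc25a1 was deleted with Elf5-Cre were compared at E12.5, in mid-gestation, to ask how the deletion affects placental development. Slc25a1 encodes the mitochondrial citrate carrier, which exports citrate to the cytosol, and Elf5-Cre drives recombination in the trophoblast lineage. The decidua and the umbilical cord had been removed before the tissue was dissociated, per the labels. Each genotype was represented by 1 library, so that every difference below is a difference between 2 libraries, without a replicate check. Genes are given as numbered matrix rows and cell kinds as numbered clusters, because the names of the rows were not used here. The level of Slc25a1 itself was not analysed here, so the genotype labels were not checked against it.

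The libraries had nearly the same depth, with 149392415 UMIs in the control and 141906904 in the knockout. Barcodes with at least 2000 UMIs that were not marked as doublets, taken as cells, numbered 9070 in the control and 9309 in the knockout and held 70.5% and 67.8% of all UMIs. The median cell had 5294 UMIs and 1725.5 detected rows in the control, and 5967 UMIs and 2040 rows in the knockout. A peak of 55154 control and 52283 knockout barcodes between 300 and 600 UMIs, taken as empty droplets, held 18.2% and 17.8% of all UMIs. Its median barcode had 494 UMIs in the control and 483 in the knockout, equal to 9.33% and 8.09% of the depth of a median cell.

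**Figure D1:**
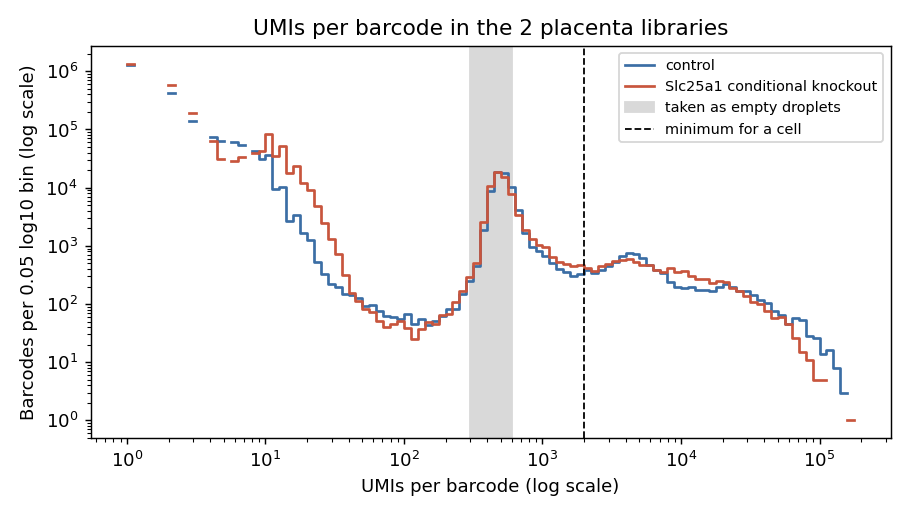
Number of barcodes (vertical axis, log scale) by UMIs per barcode (horizontal axis, log scale, bins of 0.05 on the log10 scale) in the control library (blue) and the Slc25a1 conditional knockout library (red). The grey band marks the 300 to 600 UMIs taken as empty droplets, and the dashed line the minimum of 2000 UMIs for a cell, which 9070 control and 9309 knockout barcodes passed after removal of marked doublets.

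Cells of the placenta fell into 29 clusters and 4 families of related clusters, and 1 family was clearly larger in the knockout library. Family 3, made of clusters 3, 4, 13, 19, 27 and 29, rose from 12.7% of control cells (95% interval 12.02 to 13.40) to 24.2% of knockout cells (23.29 to 25.04), a ratio of 1.90 (1.74 to 2.08). Family 4 took 9.42% of control cells (8.82 to 10.0) and 13.7% of knockout cells (13.04 to 14.44), a ratio of 1.46 that stayed below the 1.5-fold rule. Family 2 took 38.3% of control cells (37.3 to 39.3) and 29.5% of knockout cells (28.6 to 30.4), and family 1 took 39.6% (38.6 to 40.6) and 32.6% (31.7 to 33.6). The ratios of family 2 (0.771) and family 1 (0.823) were also within 1.5-fold. Family 1 was rich in 1 row, the most abundant of each library, which held 31.1% of the family's UMIs in the control and 28.1% in the knockout. That row held 0.510% and 0.626% in family 2, 1.03% and 1.02% in family 3, and 1.67% and 1.24% in family 4.

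Cells of family 2 and family 3 were the deepest. Median UMIs per cell were 12113 in the control and 10452 in the knockout for family 2, and 9754 and 9067 for family 3. They were 4444 and 4467 for family 1, whose cells had only 984 and 1122 detected rows, and 4388 and 4961.5 for family 4. Family 2 supplied 65.7% of all cell UMIs in the control and 47.3% in the knockout, and family 3 supplied 12.6% and 24.9%. The minimum for a cell bears on these shares. The ratio of family 3 was 1.72 among cells with at least 1000 detected rows, whereas that of family 1 was 0.985 there and 1.02, with its direction reversed, over every barcode of at least 200 detected rows, where clusters given to any family held only 12.2% of control and 14.5% of knockout barcodes.

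**Figure D2:**
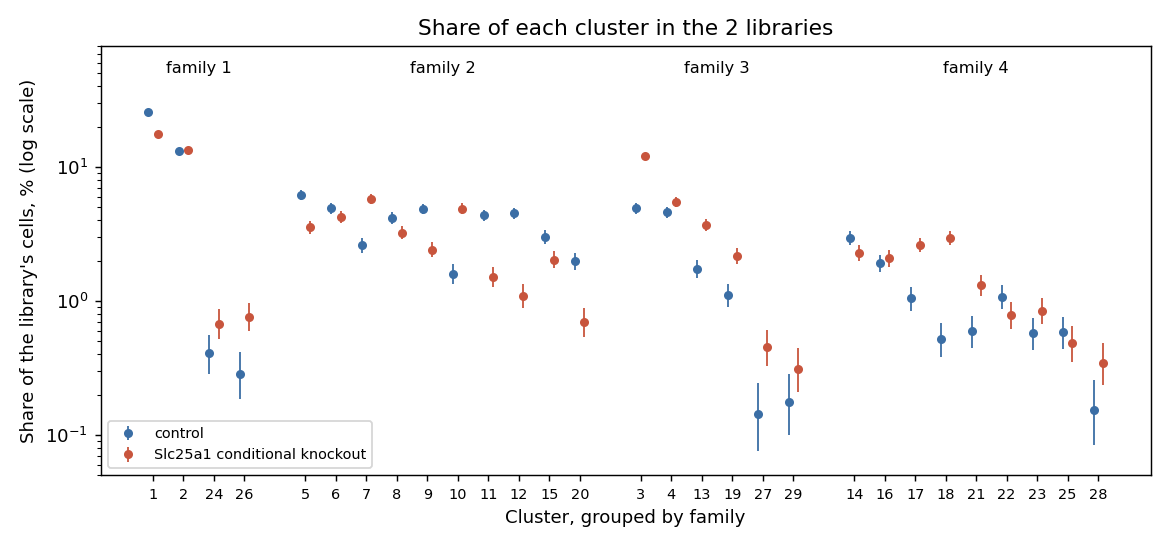
Share of each library's cells (vertical axis, %, log scale) in each of the 29 clusters (horizontal axis, grouped by family), for the control (blue) and the Slc25a1 conditional knockout (red). Bars are exact 95% binomial intervals, which cover counting error only; in family 3 each of the 6 clusters has its knockout point above its control point, although for clusters 4 and 29 the ratio was under 1.5 or the intervals overlapped.

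Within families the change was uneven. Of the 29 clusters, 15 differed at least 1.5-fold in share with separate intervals, 10 larger in the knockout and 5 smaller, and 14 did not pass the rule. Cluster 3, the most numerous of family 3, rose from 4.91% (4.47 to 5.37) to 12.1% (11.4 to 12.7), a ratio of 2.46. Cluster 13, its closest relative, rose from 1.74% (1.48 to 2.03) to 3.70% (3.32 to 4.10). Cluster 27 rose from 0.143% to 0.451%, from 13 control and 42 knockout cells. Cluster 4 of the same family had 4.62% (4.197 to 5.072) and 5.48% (5.02 to 5.96), a ratio of 1.19 that was not past the rule. In family 4, cluster 18 rose 5.72-fold (3.82 to 8.74), from 0.518% to 2.96%, though only 2.575-fold with clusters drawn from the control library alone and 3.29-fold with cells thinned to 2000 UMIs, cluster 17 rose from 1.05% to 2.63% and cluster 21 from 0.595% to 1.31%, whereas cluster 14 had 2.95% and 2.28%. The small cluster 26 of family 1 rose from 0.287% to 0.763%.

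All 5 clusters past the rule with a smaller share in the knockout belonged to family 2. Shares of 1 library depend on each other, since a gain in some clusters lowers the shares of the others and a loss raises them. A smaller or larger share therefore does not by itself show a loss or gain of those cells. Cluster 5 fell from 6.21% (5.72 to 6.72) to 3.54% (3.18 to 3.94), cluster 9 from 4.86% (4.43 to 5.33) to 2.42% (2.11 to 2.75), and cluster 11 from 4.36% to 1.51%. Cluster 12 fell from 4.53% to 1.10%, and cluster 20 from 1.98% to 0.698%. In the same family clusters 7 and 10 rose, from 2.60% to 5.80% and from 1.60% to 4.90%. Cluster 10 was the closest relative of cluster 12, and the pair together held 6.13% of control cells and 5.99% of knockout cells. Cluster 7 was likewise the closest relative of cluster 11. Of the 15 calls, those of clusters 7, 10 and 19 came within 1.5-fold in at least 1 alternative, with lowest ratios of 1.499, 1.04 and 1.38. The other 12 did not in any alternative where a matching cluster was found. Of 13 alternatives, cluster 12 was matched in only 5, cluster 26 in 7, and clusters 9, 10 and 11 in 8 each. An alternative without a match gave no check of a call. With cells thinned to equal depth, clusters 9, 10, 11 and 12 had no match. Size was less stable than direction, with ratios as high as 4.17 for cluster 7 and 5.43 for cluster 27 and as low as 1.54 for cluster 26. Cluster 1, the most numerous of all, had 25.8% of control and 17.7% of knockout cells, a ratio of 0.684 that did not pass the rule and that went from 0.165 to 0.962 over the 10 alternatives where a matching cluster was found.

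Summed over all cells, expression was close between the libraries. Across 23483 rows with UMIs in both, the log2 levels correlated with a Pearson r of 0.985, which is across genes, and genes are not independent replicates. Of 3905 rows that reached 50 CPM (UMIs of a row per 1000000 UMIs of its library's cells), 92.7% lay within 1.5-fold and 86 (2.20%) were past the rule of size, 69 higher in the knockout and 17 lower. Counting error alone gave 0 in each of 50 draws. The median ratio was 2.24 among the higher rows and 2.48 among the lower ones. TMM scaling moved the log2 ratio of every row by -0.12 and the split became 38 higher and 27 lower, and the median of ratios moved it by -0.13, with 37 and 27. Where both libraries were weighted to the same mix of clusters, 12 rows passed, 10 higher and 2 lower, of which 6 were among the 86.

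Each of the rows with the largest ratios had most of its UMIs in 1 family. Row 28802 was 4.04-fold higher in the knockout (3.89 to 4.21), at 30.4 CPM in the control (29.4 to 31.5) and 123 in the knockout (121 to 125). Family 3 held 76.2% of its UMIs in the control and 86.1% in the knockout. The row was not particular to family 3, since it stood at 92.0 and 94.1 CPM in family 4. In the small cluster 25 of family 4 it reached 552 and 681 CPM. In cluster 3 row 28802 stood at 324 and 634 CPM, just under 2-fold. It passed the rule in cluster 4, at 8.18 and 85.6 CPM, and in cluster 19 of the same family, at 14.1 and 57.8. Row 3816 was 3.10-fold higher (2.96 to 3.25), at 21.8 CPM in the control (20.9 to 22.7) and 67.6 in the knockout (66.0 to 69.3). Family 3 held 88.2% and 92.3% of its UMIs, and it was past the rule in 0 of the 22 clusters compared. At the same mix of clusters the log2 ratio of row 28802 was 1.003 in place of 2.02, and that of row 3816 was 0.59 in place of 1.63.

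Row 10175 was 33.3-fold lower in the knockout (29.0 to 38.5), at 69.6 CPM in the control (68.0 to 71.2) and 2.09 in the knockout (1.81 to 2.40). Cluster 22 of family 4 held 5837 of its 7334 control UMIs, in 63 of 98 cells, and stood at 19137 CPM in the control against 509 in the knockout. In cluster 1, of another family, 1.45% of control cells had a UMI of this row, at a median depth of 4326 UMIs against 2560.5 in cluster 22. A few cells set its level. The 10 cells with the most UMIs of this row held 89.2% of them in the control, 1 of them with 1765 UMIs, and without the 10 such cells of each library the levels were 7.50 and 1.04 CPM. Row 1299 was 3.22-fold lower (3.14 to 3.31), at 235 CPM in the control (232 to 238) and 72.9 in the knockout (71.2 to 74.6). Family 2 held 96.7% of its UMIs in the control and 94.9% in the knockout, at 346 and 146 CPM. In cluster 9 its level was 1227 and 762 CPM and in cluster 12 it was 2027 and 1204, both within 2-fold, whereas it passed the rule in cluster 20, at 127 and 58.3 CPM. In cluster 6 it was not lower in the knockout, at 262 and 303 CPM. Its log2 ratio was -1.69 as measured and -0.71 at the same mix of clusters.

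Inside clusters, differences of at least 2-fold were found in each of the 22 clusters that had at least 50 cells of both libraries. In family 1, cluster 1 had 65 rows higher and 6 lower in the knockout, and cluster 2 had 10 and 6. The median log2 ratio in cluster 1 was itself 0.26, and with TMM scaling, which moved each row there by -0.28, the split turned to 11 higher and 20 lower. In family 3, cluster 3 had 16 rows higher and 5 lower, while cluster 4, whose share changed little, had 50 and 34. In family 2, cluster 9 had 47 higher and 5 lower, cluster 6 had 41 and 5, and cluster 5 had 12 and 1. Counting error alone gave a mean of 0 rows in each of these 7 clusters. Other clusters of family 2 had more lower rows than higher ones, 53 higher and 65 lower in cluster 10, against 3.84 from counting error alone, and 32 and 65 in cluster 12, against 5.58. With TMM scaling the split reversed in cluster 10, to 76 higher and 41 lower, and kept its direction in cluster 12, at 29 and 89. In family 4, cluster 22 had 147 higher and 207 lower rows against 112 from counting error alone, and cluster 21 had 82 and 83 against 15.9.

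**Figure D3:**
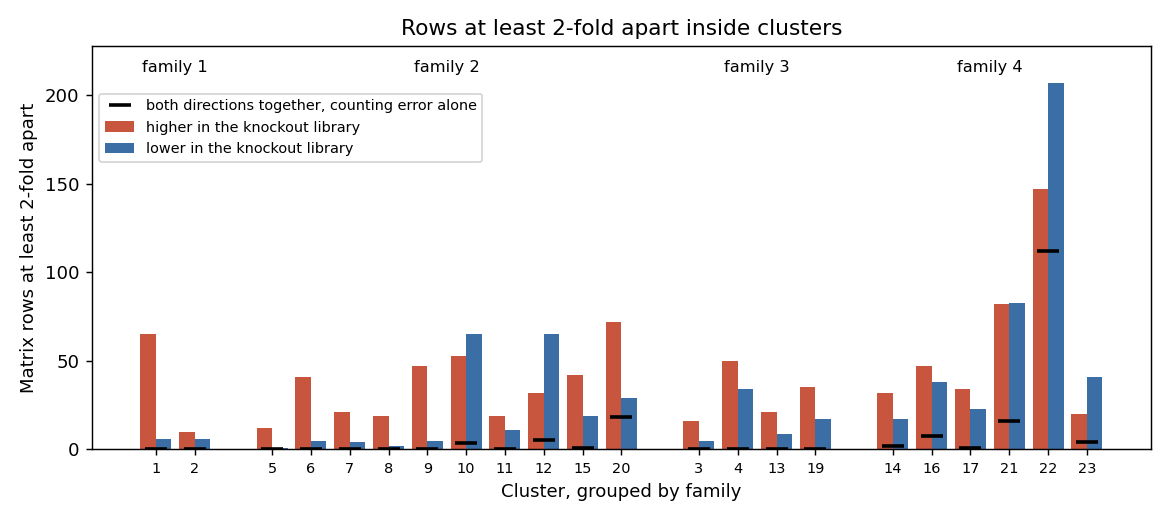
Number of matrix rows at least 2-fold apart between the libraries (vertical axis) in each of the 22 clusters compared (horizontal axis, grouped by family), higher in the Slc25a1 conditional knockout in red and lower in blue. Black marks give the mean number, both directions together, that counting error alone puts past the rule, which was 112 in cluster 22 and 0 in cluster 1; with TMM scaling the split turned to 11 higher and 20 lower in cluster 1, 76 and 41 in cluster 10, 15 and 16 in cluster 11, and 33 and 59 in cluster 20.

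Most of these rows passed in a single cluster. Over the 22 clusters there were 917 calls of a row higher in the knockout and 692 of a row lower, 1609 in all against 171 from counting error alone. Counting error leaves out the variation between cells, so the excess can include rows whose UMIs lie in few cells. Of 8872 rows that reached the level in a cluster, 597 were higher in at least 1 cluster, 487 of them in exactly 1. Of the same rows, 584 were lower in at least 1 cluster, 527 of them in exactly 1, and 37 were higher in 1 cluster and lower in another. The 110 rows higher in at least 2 clusters compare with 41.6 for independent lists, and the 57 rows lower in at least 2 with 22.4. These baselines draw each list from all 8872 rows, although a single cluster had only 1537 to 4591 rows at the level. They are therefore likely too low, and the excess cannot be sized from them. Because the clusters also share their libraries, any excess over independent lists is not by itself a shared effect of genotype. The number of calls depended on the depth of a cluster, and with all clusters thinned to 226155 UMIs per library it was 4576, of which counting error alone gave 2405.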

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

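The tests of family 3 against the minimum for a cell, doublets and the drawing of clusters, and both tests of clusters 10 and 12, were chosen after the results were seen. For doublets with cells of other families, the limit for the verdict was also set after the values were seen, and rows at least 5 times as high, tried as well, gave a median of 0.986 over 169 rows.

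The barcodes taken as empty droplets, which were not counted as cells, differed between the libraries, in part in the same rows as the cells. In them 55 rows were at least 2-fold higher in the knockout and 15 were lower, of 3065 rows that reached 50 CPM. Of 2891 rows that reached this level in both sets of barcodes, 25 were higher in cells and in empty droplets, against 0.514 for independent lists, and 8 were lower in both, against 0.0540. Both sets come from the same 2 libraries. The most abundant row held 2.43% of the UMIs of empty droplets in the control and 4.01% in the knockout, although it held 5.62% and 5.25% of those of cells. Row 28802 stood at 8.78 and 44.9 CPM in empty droplets, and row 1299 at 132 and 53.5.

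Barcodes of 600 to 2000 UMIs, also below the minimum for a cell, had 51 rows at least 2-fold higher in the knockout and 18 lower. Of the higher rows, 23 were also higher over all cells. These barcodes numbered 13761 in the control and 13829 in the knockout.

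Inside clusters, 37 rows were at least 2-fold higher in the knockout in 1 cluster and at least 2-fold lower in another, where counting error alone gave a mean of 0.55 and a highest of 2 in 20 draws. The draws leave out the variation between cells. Whether the effect of genotype differs between these clusters was not tested, because each genotype had 1 library.

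The larger share of family 3 in the knockout library was weighed against 3 technical explanations. Over 4 other minimums for a cell, of which the 2 lower ones left part of the barcodes without a family, its ratio was 1.72 to 1.98. It was 1.72 with at least 1000 detected rows and 1.98 with at least 4000 UMIs. With at least 1000 UMIs and every cluster given a family it was 1.78. These 3 values argue against the minimum as the cause. With at least 200 detected rows, clusters given to a family held only 12.2% of control and 14.5% of knockout barcodes, so that setting cannot decide. With clusters drawn from the control library alone the ratio of family 3 was 1.89, which argues against clusters that follow the library. Without the cells of family 3 in which the most abundant row held over 5% of the UMIs, as it did in 98.9% of control and 98.8% of knockout cells of family 1, the ratio was 1.91, which argues against doublets with family 1. A larger share made of barcodes from other families, doublets among them, would dilute the rows particular to family 3. These were the 273 rows at least 2 times as high in control cells of family 3 as in any control cluster outside it. If the added barcodes held no RNA of family 3 and made the whole difference, the rows would fall to 0.526 of their level. Their median was 0.983 of the control level in the knockout (quartiles 0.830 and 1.10), which argues against such barcodes. Doublets that include a cell of family 3 would dilute these rows less, so the test cannot decide on them. With 1 library per genotype, the genotype and any other difference between these 2 placental preparations, such as dissection or dissociation, cannot be told apart, and the deletion stays an untested explanation.

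Clusters 10 and 12 moved in opposite directions, 3.06-fold up and 4.14-fold down, at median depths of 3032 and 4897 UMIs in the control. With every cell thinned to 2000 UMIs, 95.8% of cluster 10 and 81.5% of cluster 12 fell into 1 cluster, with a share ratio of 1.07. A split of 1 population by depth alone is nonetheless argued against by a count on separate UMIs. The UMIs of each cell were divided at random into 2 parts, and clusters were drawn on 1 part. Those that best matched clusters 10 and 12 differed at least 2-fold in 347 rows, in the same direction in both libraries. These rows were counted in the remaining part, among cells of 3000 to 5000 UMIs, where counting error alone gave at most 4. The match of cluster 10 had 110 such cells in the control and 158 in the knockout, and that of cluster 12 had 50 and 23. Counting error leaves out the variation between cells, which matters more with so few cells. In that draw the match of cluster 12, with 41.5% of its cells, went from 1.78% to 0.666% of cells, and the match of cluster 10, which also took 43.1% of cluster 12, from 3.88% to 4.77%. Row 1299 stood at 23.5 CPM in cluster 10 and 2027 CPM in cluster 12 in the control. Both clusters were drawn on the counts that give these levels, so the levels are no separate support. Whether 2 states changed their shares in opposite directions stays open, because with clusters drawn from the control library 76.5% of cluster 10 and 53.0% of cluster 12 lay in 1 cluster.

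Rows past the rule in the same direction in at least 5 clusters numbered 33, 29 higher and 4 lower, with 264 calls, and all 33 differed in that direction in empty droplets, 18 of them past the rule. Free RNA from other cells may therefore add to them. In the library where the row was higher, the median call held 3.86 times the UMIs that free RNA would supply (quartiles 1.92 and 16.8), and 69.3% of calls remained after subtraction. The median lies past the value of 2 set beforehand as speaking against free RNA as the source, but the share of calls that remained lies under the 80% set with it, so the question stays open.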

How the results depend on the processing

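The minimums of 1000 and 4000 UMIs, the literal filter of 200 detected rows, the removal of doublet scores, the subtraction of free RNA, the equal thinning of clusters, the minimum of 100 cells the clustering without rows past the rule and the giving of every cluster to a family were tried after the data were seen. No paired analysis was possible because each genotype had 1 library, and there was no replicate to leave out. Family 3 kept a ratio between 1.72 and 1.98 in all 14 alternatives and family 4 between 1.33 and 1.59. These are not 14 separate checks. Each cluster of an alternative took the family of most of its cells of the main set. New clusters drawn on the same cells could therefore change the share of a family little. The alternative with marked doublets kept added only 3 barcodes per library, and the minimum of 1000 UMIs was counted in 2 ways. Clustered on the 1530 variable rows that were not past the rule, family 3 was at 1.90 and 16 clusters passed the share rule. The number of clusters past the share rule was 25 of 41 at Leiden resolution 2, which makes more clusters. With at least 1000 detected rows the ratio was 0.985 for family 1, 0.678 for family 2 and 1.72 for family 3, from shares of 16.2% and 27.8%; the filter removes cells with few detected rows, of which family 1 has the fewest, with medians of 984 and 1122. It was 0.774 for family 1 with at least 4000 UMIs; the cause was not tested. With at least 1000 UMIs it was 0.609 for family 2, but only 77.7% of control and 75.5% of knockout cells lay in clusters given to a family, and with every cluster given to the family of most of its cells of the main set it was 0.825 for family 2 and 1.78 for family 3. Over every barcode of at least 200 detected rows there were 78306 control and 75749 knockout barcodes, most of them empty droplets, clusters given to a family held 12.2% and 14.5% of them, and the ratio was 1.02 for family 1, reversed, and 0.983 for family 2.

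The count of 86 rows over all cells stayed within 1.5 times in 11 of 16 alternatives. It was 346 at a minimum of 10 CPM, 19 at 200, 284 at a ratio of 1.5, 6 at a ratio of 3, and 12 at the same mix of clusters. The 1609 calls inside clusters stayed within 1.5 times in 10 of 17. They were 2786 with cells of at least 1000 UMIs, 6362 at a minimum of 10 CPM, 294 at 200, 5735 at a ratio of 1.5, 441 at a ratio of 3, 871 in the 17 clusters with at least 100 cells of each library, and 4576 with clusters thinned to 226155 UMIs, where counting error alone gave 2405. Lower and looser limits admit more rows by construction. Depth limits clusters 20, 21 and 22 most, where counting error alone gave 18.1, 15.9 and 112 calls. All 4 named rows kept their direction in the 12 alternatives that change their ratio; the other 4 change only the limits of the rule.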

Other observations

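The test of shared differences below was planned before its result was seen, and the view of every barcode of at least 200 detected rows was added after the data were seen. Cluster 19 of family 3, whose share went from 1.11% to 2.16%, also differed in depth, with a median of 10829 UMIs and 3715 detected rows in the control and 4989 UMIs and 2356 rows in the knockout. Cells of the 2 largest clusters of the same family were closer in depth, at 12785 and 10305 UMIs in cluster 3 and 5583 and 5519 in cluster 4. Cluster 23, the closest relative of cluster 18, had 0.573% of control cells (0.428 to 0.751) and 0.849% of knockout cells (0.672 to 1.06), a ratio of 1.48 that was not past the rule. Cluster 18 was deep in both libraries, at 18557 and 16594.5 UMIs, and its rows were not compared, since it had only 47 control cells. Cluster 16 differed little in share, at 1.91% and 2.08%, yet had 47 rows higher and 38 lower in the knockout, against 7.50 from counting error alone.

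When every barcode of at least 200 detected rows was clustered, the 5 largest clusters, all at the depth of empty droplets, differed in share between the libraries, although each held barcodes of both. A cluster with a median of 523.5 UMIs held 4.98% of control and 30.7% of knockout barcodes, and the clusters with medians of 481, 527 and 491 UMIs held 29.4% and 12.1%, 24.2% and 11.6%, and 11.004% and 4.72%. The cluster with a median of 495 UMIs, at 15.2% and 22.2%, had a ratio of 1.46 that was not past the rule. A small cluster at this depth, with a median of 307 UMIs, held 0.0332% of control and 0.0277% of knockout barcodes, with intervals that overlapped.

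A hypothesis was that differences between the libraries are shared by related clusters. After subtraction of free RNA, log2 ratios across rows with at least 100 UMIs in both libraries correlated with a mean r of 0.222 (SD 0.172) over 67 pairs of clusters within a family and 0.124 (SD 0.115) over 164 pairs between families. The difference of 0.0985 lay just under the bound of 0.1 set beforehand, so by that bound the hypothesis was not met. The margin was small against the spread of the pairs. Without subtraction of free RNA the means were 0.270 within families and 0.170 between them. The mean was thus higher within families either way. All pairs rest on the same 2 libraries, however, so the data give no firm answer on whether clusters of 1 family share their differences more than others do. Pairs share clusters and all pairs share the 2 libraries, so they are not independent, and genes are not independent replicates.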
